A study of Mus musculus with 8 samples.

How the data were processed

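Skeletal muscle RNA was sequenced from diet-induced obese C57BL/6 mice, an inbred strain made obese by feeding. Per the labels, the mice were 24 weeks old and 8 were assigned to each group, of which 4 per group were sequenced, giving 8 libraries. The liraglutide group received 0.2 mg/kg liraglutide, a GLP-1 receptor agonist, under the skin each day for 9 weeks, and the group called model received saline. Each library has its own animal code in the labels, so the replicates were separate animals. Total RNA was extracted with TRIzol and made into stranded libraries from polyadenylated RNA, per the labels' protocols.

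The deposited table gives, for each of 22173 genes and 8 libraries, a raw count and an FPKM value (fragments scaled by gene length and library total), per the file headers. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq without versions. They also name the human build GRCh38, although 21979 of the genes carried an identifier of the mouse RefSeq annotation and 21948 carried the matching symbol; the build used is therefore open and no coordinates are given. The deposited FPKM equalled the deposited count divided by the library total and by a whole-number gene length for 17484 of the 17484 genes with a count, within 0.01 base. Genes of the mitochondrial genome were absent from the table, so a list of them (26 symbols, 0 found) was not tested, nor was the B and plasma cell list (6 of 9 in the table, under 3 tested). A column name with a misspelt group was assigned through its animal code. No column of per-sample values was left unused.

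Because raw counts were present, edgeR 4.0.16 in R 4.3.3 took the place of limma on FPKM, a substitution laid down before the data were examined. The quasi-likelihood test was run on the counts with TMM scaling and the filterByExpr filter (minimum count 10), which left 12963 genes. Adjusted p values are Benjamini-Hochberg values over these genes, and a call means an adjusted p under 0.05. A looser criterion was an unadjusted p under 0.05 with a change of at least 1.5-fold. Log2 fold changes are liraglutide minus model. FPKM values are given as mean ± SD with n = 4 per group. Library totals ran from 15033631 to 18244579 counts, and 3 counts, the floor used here for a gene at 0, stand for 0.0425 CPM over the liraglutide group and 0.0469 CPM over the model group. The common biological coefficient of variation was 13.7%.

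The gene lists, the cell type marker lists, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. The 36 testable lists (23 of pathways and functions, 13 of cell types) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted together. Camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean per library were run beside it. With 4 against 4 libraries there are 70 assignments, so the smallest two-sided exact p is 0.0286. Pathway terms came from the GO and KEGG columns of the deposited table, with 15 to 300 tested genes each, which gave 2456 terms. For 2121 genes with GO entries and 16 with KEGG entries the identifiers and names differed in number, and their names were taken from the same identifiers elsewhere in the table; this reading was adopted after a first count of called terms had been seen.

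Genes were named by a fixed rule: the 10 largest called changes in each direction with a mean of at least 1 FPKM in a group and no overlap between groups, the 3 members with the smallest p from each called list, 1 from every other list, and the receptors Glp1r, Gipr and Gcgr. Trf, Fasn, Scd1, Fabp4, Fabp3, Plin1, Cfd, Col4a1, Postn, Fbxo32, Slc2a4, Hspa1b, Myh4, Apoa1 and the other genes of other tissues outside that rule were named after their values were seen. Lists of epididymis, hepatocyte, mesothelium, testis, and seminal vesicle and prostate markers were also written after values of some of these genes had been seen. For the 10 largest falls, the epididymis markers and the 3 receptors, ratios of summed CPM (counts scaled to the library total) with exact 95% intervals are given in place of fitted folds, and a count of 0 was set to 3 counts over the group for a lower bound. These intervals cover counting error only. Some genes named by these rules are not reported here, although all counts of genes include them.

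Alternatives fixed in advance were other pseudocounts, filters, scalings, variance models, DESeq2 1.42.0, the replicate number as a block, and omission of each library in turn. The pseudocount, rescaling, quantile, no-trend and array-weight alternatives ran in limma on log2 FPKM with a pseudocount of 1 or 0.1, so they change the tool as well. Offsets for gene length and for length with GC content (a loess smooth, span 0.5; GC known for 12897 tested genes, 99.5%), limma on log2(FPKM + 1), omission of liraglutide 2 with model 3, and omission of the epididymis markers were added after the data had been seen. On simulated counts for the 4 against 4 comparison over 12822 genes, edgeR recovered 2 of 50 genes changed 1.2-fold, 34 of 50 at 1.5-fold, 43 of 50 at 2-fold and 49 of 50 at 4-fold, with 6 false calls. A list raised 1.2-fold in simulation was called with 0 other lists called of the 36 tested. A simulated length trend alone called 6 lists without the length offset and 0 with it. Simulated genes varied independently, whereas the estimated correlation of the real oxidative phosphorylation list was 0.339, and the simulated trend was linear in log2 length. These counts of 0 therefore do not cover false calls among correlated genes or trends of another shape.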

Results

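Transcript levels were measured by RNA sequencing in skeletal muscle of 8 diet-induced obese mice, 4 given liraglutide for 9 weeks and 4 given saline (the model group). The comparison addresses how liraglutide treatment alters the muscle transcriptome in obesity. Counts per library totalled 17133476 to 18244579 in the liraglutide group and 15033631 to 16622716 in the model group, ranges that did not overlap (exact permutation p = 0.0286, two-sided, the smallest possible with 4 against 4). Of 22173 genes, 4689 had 0 counts in all libraries and 12963 were tested.

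Muscle of liraglutide-treated mice had higher levels of nuclear-encoded oxidative phosphorylation genes, cytosolic ribosomal protein genes and citric acid cycle genes, by about 1.15-fold to 1.21-fold at the list medians. These calls were lost in camera at adjusted p = 0.184, 0.184 and 0.256 with an estimated correlation, and with a gene length offset the log2 medians of the oxidative phosphorylation and ribosomal lists went from 0.28 and 0.27 to 0.12 and 0.10. Adipocyte markers, lipogenic and cholesterol synthesis genes and extracellular matrix genes were lower, calls lost in camera at adjusted p = 0.256, 0.184, 0.184 and 0.312 with an estimated correlation. Leptin (Lep) fell to 26.8 ± 7.12 FPKM from 85.1 ± 18.6 (SD, n = 4 per group). The largest falls were in genes of the epididymis, such as Gpx5, at 2 to 12 counts per liraglutide library against 168 to 449 per model library. An effect of treatment on these genes could not be told apart from tissue carried over at dissection in the model libraries. The largest rise by the fixed rule was in Prtn3, a neutrophil granule protease. The tendon genes Chad and Comp rose about 3-fold (3.18-fold and 3.03-fold). The call of Prtn3 ended on leaving out any 1 of 6 libraries, and that of Chad on leaving out 1.

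The quasi-likelihood test of edgeR called 1333 genes, 707 higher and 626 lower with liraglutide (10.3% of those tested). The median fold of the calls was 1.22 upward and 1.43 downward; 33 higher and 274 lower genes passed 1.5-fold, and 16 and 148 passed 2-fold. At an unadjusted p under 0.05, 3436 genes passed against 648 given by chance, and 589 of them also changed at least 1.5-fold (110 higher, 479 lower). Groups did not overlap for 2371 tested genes (18.3%, against 2.86% by chance), 1286 of them called. The share of calls that were higher, 53.0%, depended on the scaling: raw library sizes gave 338 higher and 1241 lower, limma on FPKM rescaled to a common sum gave 260 and 2136 with the median of all genes moved from -0.01 to -0.13, limma on log2(FPKM + 1) gave 379 and 1090, and a length and GC offset gave 173 and 286. Leaving out model 1 gave 615 calls, model 2 gave 713, model 4 gave 731 and liraglutide 3 gave 862. Without liraglutide 2 and model 3, which stood apart in transcripts of other tissues, there were 697 calls, 613 of them among the 1333. The model libraries kept in this fit still held epididymis transcripts, at 650 to 1177 counts per library without Crisp1.

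Oxidative phosphorylation genes, which encode subunits of the respiratory chain and ATP synthase, rose together. Of 79 measured, 62 rose and 0 fell (72 and 0 adjusted over the list alone), with a median log2 fold change of 0.28 and a camera adjusted p of 7.83e-46 (adjusted p = 0.184 with an estimated correlation). Ndufb8 (Entrez gene 67264), a complex I subunit, rose from 111 ± 3.37 to 148 ± 4.16 FPKM (SD, n = 4; log2 fold change 0.49 ± 0.039 SE, edgeR adjusted p = 0.00057). Cox6a2, the muscle form of a cytochrome c oxidase subunit, rose from 783 ± 9.52 to 992 ± 22.1 FPKM, and the complex I subunit Ndufb11 rose 1.32-fold. Among 58 cytosolic ribosomal protein genes, 44 rose and 0 fell (54 and 0 adjusted over the list alone; median 0.27, camera adjusted p = 5.58e-35, adjusted p = 0.184 with an estimated correlation). Rps14 rose 1.36-fold, Rps29 1.41-fold and Rplp1 1.34-fold. The citric acid cycle list had 13 of 22 genes higher and 0 lower (14 and 0 adjusted over the list alone; median 0.20, camera adjusted p = 3.39e-08, adjusted p = 0.256 with an estimated correlation). Its members Sdhb, Mdh2 and Idh3b, of succinate dehydrogenase, malate dehydrogenase and isocitrate dehydrogenase, rose 1.29-fold, 1.25-fold and 1.21-fold. The median gene length of the oxidative phosphorylation and ribosomal lists was 795 and 814 bases. The correlation of a library's deviation with gene length across genes was -0.264 to -0.0198 in the liraglutide libraries and 0.158 to 0.225 in the model libraries. The same correlation with GC content was 0.167 to 0.236 in the liraglutide libraries and -0.266 to -0.126 in the model libraries. With a gene length offset the medians were 0.12 for oxidative phosphorylation (26 genes higher) and 0.10 for ribosomal proteins (13 higher), and with GC content added the calls of Rps14 (adjusted p = 0.0654) and Rplp1 (adjusted p = 0.138) ended; under quantile normalization the citric acid cycle call ended at a median of 0.014. Leaving out model 1 or model 2 left 7 citric acid cycle genes higher.

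**Figure D1:**
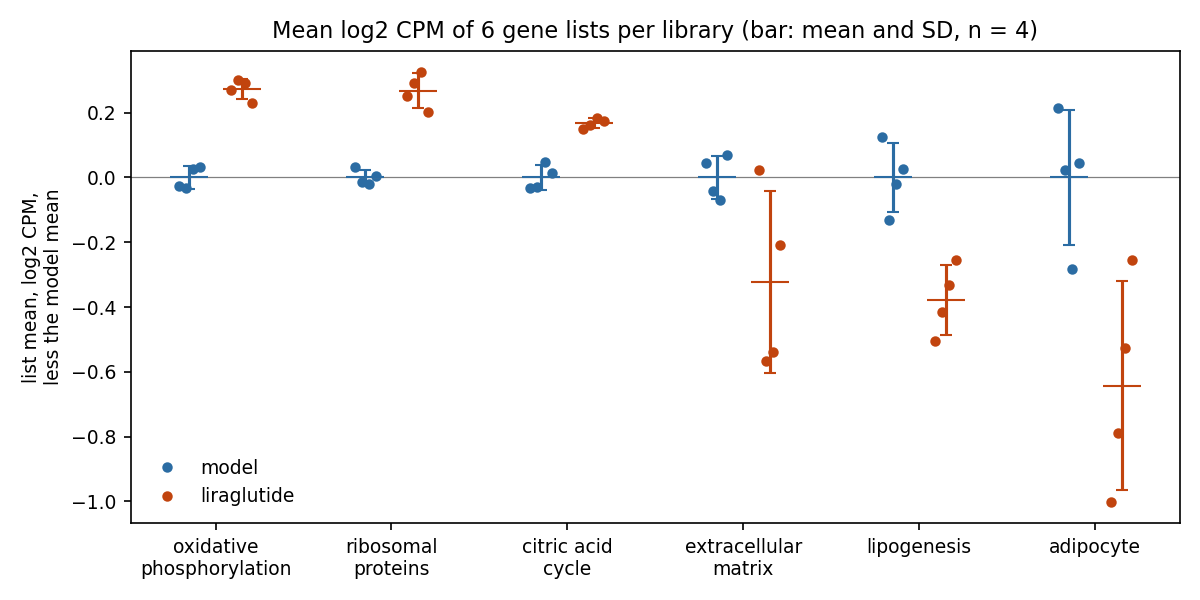
Mean log2 CPM of 6 gene lists in each library, less the mean of the model libraries; points are libraries and bars are the mean and SD of 4 libraries. Oxidative phosphorylation, ribosomal protein and citric acid cycle means were higher in each liraglutide library than in each model library, whereas the adipocyte and extracellular matrix means overlapped between the groups.

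Genes of glycolysis and of fast fibres were modestly higher in the liraglutide group. In the glycolysis and glycogen list 11 of 28 rose and 1 fell (15 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 3.38e-05, adjusted p = 0.198 with an estimated correlation), including Aldoa (aldolase, 1.21-fold), Eno3 (muscle enolase, 1.21-fold) and Pgam2 (1.17-fold). The insulin-responsive glucose transporter Slc2a4 rose from 122 ± 5.21 to 133 ± 7.19 FPKM (SD, n = 4, edgeR adjusted p = 0.0437). Slc2a4, the 1 insulin signalling gene called higher, lost its call without liraglutide 2, liraglutide 3 or any single model library. Of 15 fast fibre genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.13, camera adjusted p = 0.000136, adjusted p = 0.291 with an estimated correlation). The troponin genes Tnnc2 and Tnni2 rose 1.29-fold and 1.22-fold and the myosin light chain gene Mylpf 1.13-fold, while Myh4, the main fast myosin heavy chain, stood at 10414 ± 493 against 10995 ± 311 FPKM (log2 fold change -0.0031). In the fatty acid uptake and oxidation list 9 of 32 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.10, camera adjusted p = 0.014, adjusted p = 0.673 with an estimated correlation). Etfb, Acads and Fabp3 rose 1.22-fold, 1.17-fold and 1.30-fold, whereas the fatty acid translocase Cd36 fell by 0.54 on the log2 scale. The medians of the glycolysis, fast fibre and fatty acid lists turned negative under quantile normalization, at -0.013, -0.029 and -0.0027. With the length and GC offset the fast fibre call ended (median 0.052, adjusted p = 0.126), as did those of Tnni2 (0.363), Mylpf (0.997) and Pgam2 (0.846) and of the fatty acid list (0.105), which also ended without liraglutide 3 (0.173); the call of Acads ended without model 2 (0.0554). Leaving out model 1, model 2, model 3 or model 4 left 4, 6, 7 and 5 glycolysis genes higher, model 3 or model 4 left 3 fast fibre genes higher. Omission of liraglutide 3, model 1, model 2 or model 4 left 5, 2, 1 and 3 fatty acid genes higher. Fabp3 was not among those left without model 1 or without model 2.

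Adipocyte markers were lower with liraglutide. Of 14 measured, 8 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.73, camera adjusted p = 9.82e-09, adjusted p = 0.256 with an estimated correlation). Lep (Entrez gene 16846) fell by 1.59 on the log2 scale (SE 0.208, edgeR adjusted p = 0.00278), the adipokine gene Adipoq fell by 0.89, the amino acid transporter gene Slc7a10 by 0.87, the lipid droplet gene Plin1 by 0.79 and the fatty acid binding protein gene Fabp4 by 0.67. The adipsin gene Cfd did not pass, at 122 ± 28.8 against 112 ± 31.2 FPKM (SD, n = 4). In the lipogenesis and lipid droplet list 12 of 30 fell and 1 rose (17 and 2 adjusted over the list alone; median -0.38, camera adjusted p = 9.79e-08, adjusted p = 0.184 with an estimated correlation). Pnpla3 fell from 5.37 ± 0.82 to 1.76 ± 0.622 FPKM (SD, n = 4), and Dgat2 and Agpat2, enzymes of triglyceride synthesis, fell by 0.78 and 0.75. The fatty acid synthase gene Fasn and the desaturase gene Scd1 fell by 1.28 and 1.03. In the cholesterol synthesis list 7 of 20 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.19, camera adjusted p = 0.00153, adjusted p = 0.184 with an estimated correlation), among them Insig1 (-1.20) and Hmgcs1 (-0.49). Adipocyte counts summed to 1051 to 1529 CPM in the liraglutide and 1693 to 2609 CPM in the model libraries. Whether the lower lipogenic and cholesterol synthesis genes, and Cd36, reflect fewer adipocyte transcripts or a change within muscle fibres was not tested. Single omissions lowered the number of genes called lower to 3 to 5 for the adipocyte list (3 without model 1, model 2 or model 4, 4 without liraglutide 1, 5 without liraglutide 2 or liraglutide 3). They lowered it to 6 for lipogenesis (without liraglutide 3, model 1 or model 4). They lowered it to 2 to 4 for cholesterol synthesis (2 without model 1 or model 4, 3 without liraglutide 1 or model 3, 4 without liraglutide 2 or liraglutide 3). The cholesterol synthesis median was -0.29 without liraglutide 2. The calls of Insig1 ended without model 1 (edgeR adjusted p = 0.0599) or model 4 (0.0559), and that of Hmgcs1 with the length and GC offset (0.0553). The 3 adipocyte genes left without model 1, model 2 or model 4 were Lep, Adipoq and Slc7a10, so the calls of Plin1 and Fabp4 ended there.

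Extracellular matrix genes were lower as well, beside the adipocyte markers with their median of -0.73, and a shared origin in fat was not tested. Of 33 measured, 12 fell and 0 rose (16 and 1 adjusted over the list alone; median -0.39, camera adjusted p = 3.06e-09, adjusted p = 0.312 with an estimated correlation). Sparc (Entrez gene 20692), a collagen-binding glycoprotein, fell from 250 ± 35.2 to 118 ± 20.8 FPKM (SD, n = 4; log2 fold change -1.01 ± 0.128 SE, edgeR adjusted p = 0.00246). The basement membrane genes Nid1 and Col4a1 fell by 0.70 and 0.61, the fibrillar collagen gene Col5a2 by 0.79 and the periostin gene Postn by 0.64. Of 12 markers of fibro-adipogenic progenitors, the connective tissue cells of muscle, Dpt and Dpp4 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.16, camera adjusted p = 0.00756, adjusted p = 0.484 with an estimated correlation), while Pdgfra stood at 4.63 ± 0.169 against 5.59 ± 0.42 FPKM without a call. In the list of secreted muscle factors 3 of 14 fell and 0 rose (6 and 2 adjusted over the list alone; median -0.23, camera adjusted p = 0.0221, adjusted p = 0.198 with an estimated correlation). These were Sparc, the growth factor gene Igf1 (-0.62) and the myostatin gene Mstn (-0.29). Tendon markers moved the other way: 2 of 9 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.72, camera adjusted p = 3.77e-05, adjusted p = 0.302 with an estimated correlation), namely Chad and Comp, with Thbs4 at 54.9 ± 15.3 against 35 ± 7.14 FPKM. The progenitor list was not called without liraglutide 3 (adjusted p = 0.0686) and the secreted factor list not with limma on log2(FPKM + 1) (0.0926). Without liraglutide 2 the median of the secreted factor list was -0.099 and that of the matrix list -0.25. In all, 7 matrix genes were lower without model 1, model 2 or model 4, and 5 tendon genes were higher without liraglutide 3. Calls of single genes that ended on leaving out a library were those of Chad (without model 1, 0.0553), of Mstn (without any library but model 4, up to 0.106) and of Dpp4 (without any library but liraglutide 1, up to 0.115).

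Stress and regeneration genes rose in part. All 16 heat shock genes measured had positive log2 fold changes, of which Hspb8, Hspe1 and Cryab passed (3 higher and 0 lower; 10 and 0 adjusted over the list alone; median 0.31, camera adjusted p = 7.6e-06, adjusted p = 0.443 with an estimated correlation). Cryab rose from 378 ± 50.9 to 549 ± 104 FPKM (SD, n = 4), and the inducible Hspa1b, at 42.4 ± 23.9 against 12.5 ± 8.13 FPKM, did not pass. In the myogenesis and regeneration list 2 of 22 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.25, camera adjusted p = 0.00646, adjusted p = 0.184 with an estimated correlation); Myod1, a myogenic transcription factor, rose 1.69-fold and Des 1.21-fold while Igf1 fell by 0.62. Among 20 immediate early genes Egr1 alone rose and 0 fell (3 and 0 adjusted over the list alone; median 0.50, camera adjusted p = 0.0101, adjusted p = 0.608 with an estimated correlation), with 600 to 4124 counts against 277 to 772, and Jun and Ier3 did not pass. In the inflammation list, which was not called, Socs3 rose 6.96-fold, with 109 to 1182 counts against 44 to 123. Without liraglutide 2, 11 heat shock, 6 myogenesis and 5 immediate early genes were higher. Myogenesis had 1 higher without liraglutide 3, model 1, model 2 or model 4. Heat shock had 0 in edgeR without model 1 or model 2 and 5 without model 4. The immediate early list had 0 without liraglutide 1, model 1 or model 4, 2 without liraglutide 3, and a median of 0.31 without model 2. The immediate early list was not called without liraglutide 1 (adjusted p = 0.152) or liraglutide 4 (0.111). Calls also ended for Egr1 without liraglutide 1, liraglutide 4, model 1, model 2 or model 4 (up to 0.0897), and for Socs3 without any library but liraglutide 2 or liraglutide 3 (up to 0.103). They ended for Myod1 without liraglutide 3 or any model library (adjusted p up to 0.0682), for Hspb8 without model 1 or model 2 (0.0591 and 0.0583), for Hspe1 without liraglutide 1, model 1, model 2 or model 3 (up to 0.0647) and for Cryab without liraglutide 3, liraglutide 4, model 1 or model 2 (up to 0.0783).

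Neutrophil and macrophage lists were called without called members. All 9 neutrophil markers measured had positive log2 fold changes (0 called in either direction, also 0 adjusted over the list alone; median 0.96, camera adjusted p = 0.00756, adjusted p = 0.596 with an estimated correlation), and Retnlg, a neutrophil secreted protein, stood at 8.94 ± 2.05 against 4.48 ± 2.89 FPKM (SD, n = 4), with 2 counts in model 2 and 50 to 64 in the other model libraries. Without model 2 the neutrophil median was 0.50 (camera adjusted p = 0.0307). Of 16 macrophage markers, 13 had negative log2 fold changes (0 called in either direction, also 0 adjusted over the list alone; median -0.22, camera adjusted p = 0.0334, adjusted p = 0.673 with an estimated correlation); Cd163 stood at 7.01 ± 0.848 against 10 ± 1.8 FPKM. The macrophage call ended without liraglutide 2 (adjusted p = 0.131), liraglutide 3 (0.11), liraglutide 4 (0.21), model 1 (0.104) or model 3 (0.0504). Without liraglutide 1, whose macrophage mean was 4.491 log2 CPM against 3.602 to 3.662 in its group, the median was -0.45 with 6 of 16 markers called lower (camera adjusted p = 1.5e-09).

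Genes of the epididymis, a duct of the male reproductive tract, made up most of the largest falls. Carried-over tissue in the model libraries was not told apart from an effect of treatment on these genes. Gpx5 (Entrez gene 14780), an epididymal glutathione peroxidase, had 26 counts over the liraglutide libraries and 1310 over the model libraries, a 55.6-fold ratio of CPM (exact 95% interval 37.7 to 85.4; edgeR adjusted p = 0.00047). Rnase9 had 0 counts against 115, at least 42.3-fold lower against 3 counts over the group. Lcn5 had 3 against 267 counts (ratio 98.1, 33.2 to 479), Adam7 13 against 543 (46.1, 26.7 to 87.1) and Cst11 1 against 58 (64, 11 to 2569). Lcn8, Lcn9, Defb20 and Spag11b had 3 to 10 counts against 112 to 285. C4bp, which encodes a complement-binding protein, had 4 against 156 counts, of which 83 lay in model 3. Of 29 epididymis markers in the table, in a list written after several had been seen, 16 were tested and 12 were called lower. They summed, without Crisp1, to 14.1 ± 19.8 CPM in the liraglutide and 62.1 ± 13.8 CPM in the model libraries (SD, n = 4; exact permutation p = 0.0571). The 12 markers called lower held 4 to 38 counts per liraglutide library and 456 to 994 per model library; the overlap of the sum came from other markers in liraglutide 2, such as Serpina1f (310 counts) and Cuzd1 (291). In liraglutide 2, Crisp1 had 2635 counts, against 2 to 20 in the other liraglutide libraries.

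**Figure D2:**
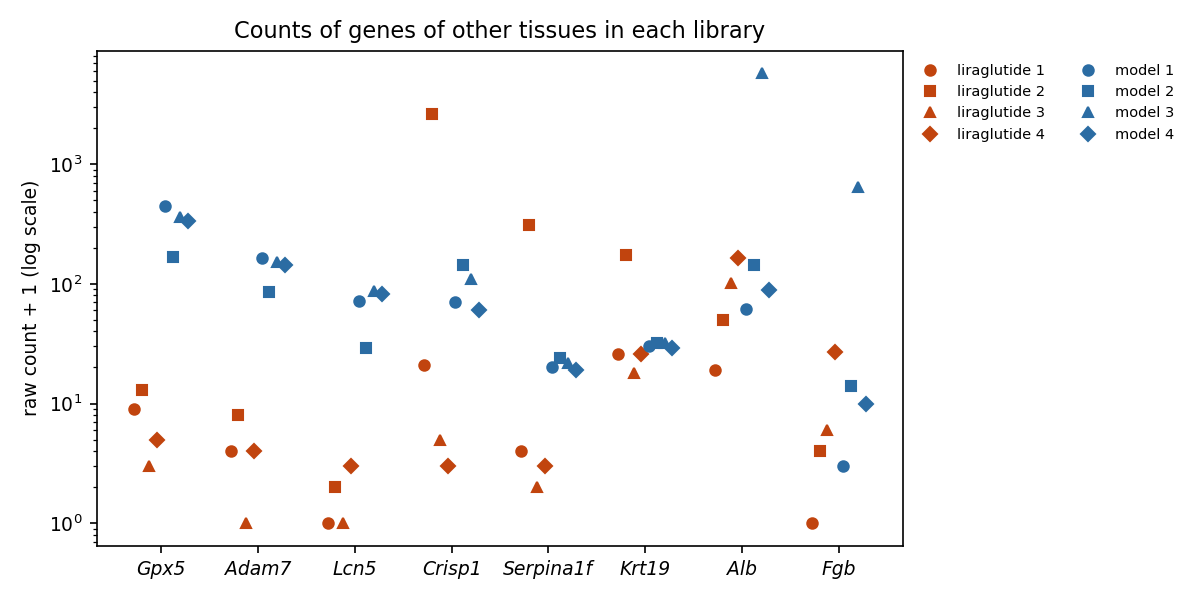
Raw counts plus 1, on a log scale, of 8 genes of other tissues in each library; colours give the group and shapes the replicate number. Gpx5, Adam7 and Lcn5 were higher in each model library, Crisp1, Serpina1f and Krt19 were highest in liraglutide 2, and Alb and Fgb were highest in model 3.

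Further rises under the fixed rule, which leaves out genes whose groups overlap such as Socs3 and Egr1, included the following genes. Prtn3 (Entrez gene 19152) rose from 0.707 ± 0.501 to 3.57 ± 2.08 FPKM (SD, n = 4; edgeR adjusted p = 0.0442). Ly6c2, a surface antigen of monocytes, rose 2.63-fold, Selp, which encodes P-selectin, 2.24-fold and Bcl3, a regulator of NF-kB, 2.42-fold. Angptl7, Rnaset2b and Osgin1 rose 2.33-fold, 1.98-fold and 1.81-fold. Leaving out single libraries ended the calls of Prtn3 (without any but liraglutide 1 or liraglutide 4; adjusted p up to 0.11), of Bcl3 (without any but liraglutide 2 or liraglutide 3; up to 0.0862) and of Rnaset2b (without any but liraglutide 2 or liraglutide 3; up to 0.117). The same held for Ly6c2 (without liraglutide 2, liraglutide 3, model 1 or model 3; up to 0.0879), Selp (without liraglutide 1, liraglutide 4, model 1 or model 2; up to 0.0718) and Angptl7 (without model 1; 0.0529). DESeq2 did not call Prtn3 (adjusted p = 0.0558).

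The GLP-1 receptor gene Glp1r had 0 counts in all 8 libraries, which allows up to 0.0425 CPM over the liraglutide group and 0.0469 CPM over the model group. The related receptor genes were too low to be tested. Gipr had 18 counts in the liraglutide and 35 in the model libraries (model over liraglutide 2.14, exact 95% interval 1.18 to 4.02), and Gcgr had 4 and 14 (3.86, 1.21 to 16.1), 8 of the 14 in model 3, the library with liver transcripts.

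Camera at the preset correlation called 18 lists and left 18 uncalled; of the latter, fry called neuromuscular junction (adjusted p = 0.00352) and calcium handling (0.0274). With single omissions camera called slow fibre without liraglutide 2 (median 0.31, adjusted p = 0.00715) or model 4 (median 0.27, 0.033), and inflammation without liraglutide 2 (0.00818) or liraglutide 3 (0.0197). The same held for antioxidant defence without liraglutide 2 (0.0169) or liraglutide 4 (0.0385), calcium handling without liraglutide 2 (0.0267) or model 4 (0.033), interferon response without model 2 (0.0434) and neuromuscular junction without liraglutide 3 (0.043). In the muscle atrophy and autophagy list 3 of 36 genes rose and 3 fell (5 and 3 adjusted over the list alone; median -0.0030), but 2 and 0 without model 1, 1 and 1 without model 2, 1 and 2 without model 3, 2 and 1 without liraglutide 1, and 3 and 1 without liraglutide 2. The ubiquitin gene Ubb rose 1.22-fold and the atrophy ligase gene Fbxo32 fell by 0.49. In the insulin signalling list 1 of 28 rose and 1 fell (3 and 2 adjusted over the list alone); in edgeR 0 rose without liraglutide 2, liraglutide 3 or any model library, 2 rose without liraglutide 4, and 3 fell without liraglutide 3. The slow fibre list (median 0.17, and -0.015 without liraglutide 3) had 1 higher gene, Mb, which encodes myoglobin (0 adjusted over the list alone; the call of Mb ended without any library but liraglutide 2 or model 3, at up to 0.118). The unfolded protein and integrated stress response list had 2 higher and 2 lower genes of 24 (3 and 2 adjusted over the list alone), with the serine synthesis gene Psat1 lower by a log2 fold change of -0.94. In edgeR 0 of its genes were higher without liraglutide 1, liraglutide 4, model 2, model 3 or model 4, and 1 was higher without model 1; 1 was lower without liraglutide 1, liraglutide 3, model 1 or model 2. The calcium handling list had 5 higher and 2 lower of 27 (8 and 2 adjusted over the list alone), with Cacnb1 1.23-fold higher, and 3 higher without any single model library; 1 was lower without liraglutide 1, liraglutide 3, model 2, model 3 or model 4. The mitochondrial biogenesis list had 3 higher of 23 (6 adjusted over the list alone), with the mitophagy kinase gene Pink1 1.29-fold higher. The antioxidant list had 3 higher and 1 lower of 22 (5 and 1 adjusted over the list alone), with Sod1 1.24-fold higher, and 5 higher without liraglutide 4 and 2 lower without liraglutide 3. Rapsn rose 1.40-fold in the neuromuscular junction list (1 of 12, also 1 adjusted over the list alone), and Rgs5 fell by 0.30 in the smooth muscle and pericyte list (1 of 10, also 1 adjusted over the list alone), whose median was 0.00086 while its test pointed down. The inflammation list had 1 higher of 25 (0 adjusted over the list alone), and 2 without liraglutide 2 or liraglutide 3. The interferon, circadian clock, endothelial, T cell, Schwann cell, brown adipocyte, erythroid and keratinocyte lists had 0 called genes in edgeR (0 in each adjusted over the list alone except 1 lower in the T cell list). Their genes of smallest p were Ifi27l2a, Dbp, Tek, Il7r, Ncmap, Otop1, Hba-a2 and Krt10, with unadjusted p of 0.00672, 0.00851, 0.0171, 0.00679, 0.116, 0.0134, 0.0823 and 0.703.

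**Figure D3:**
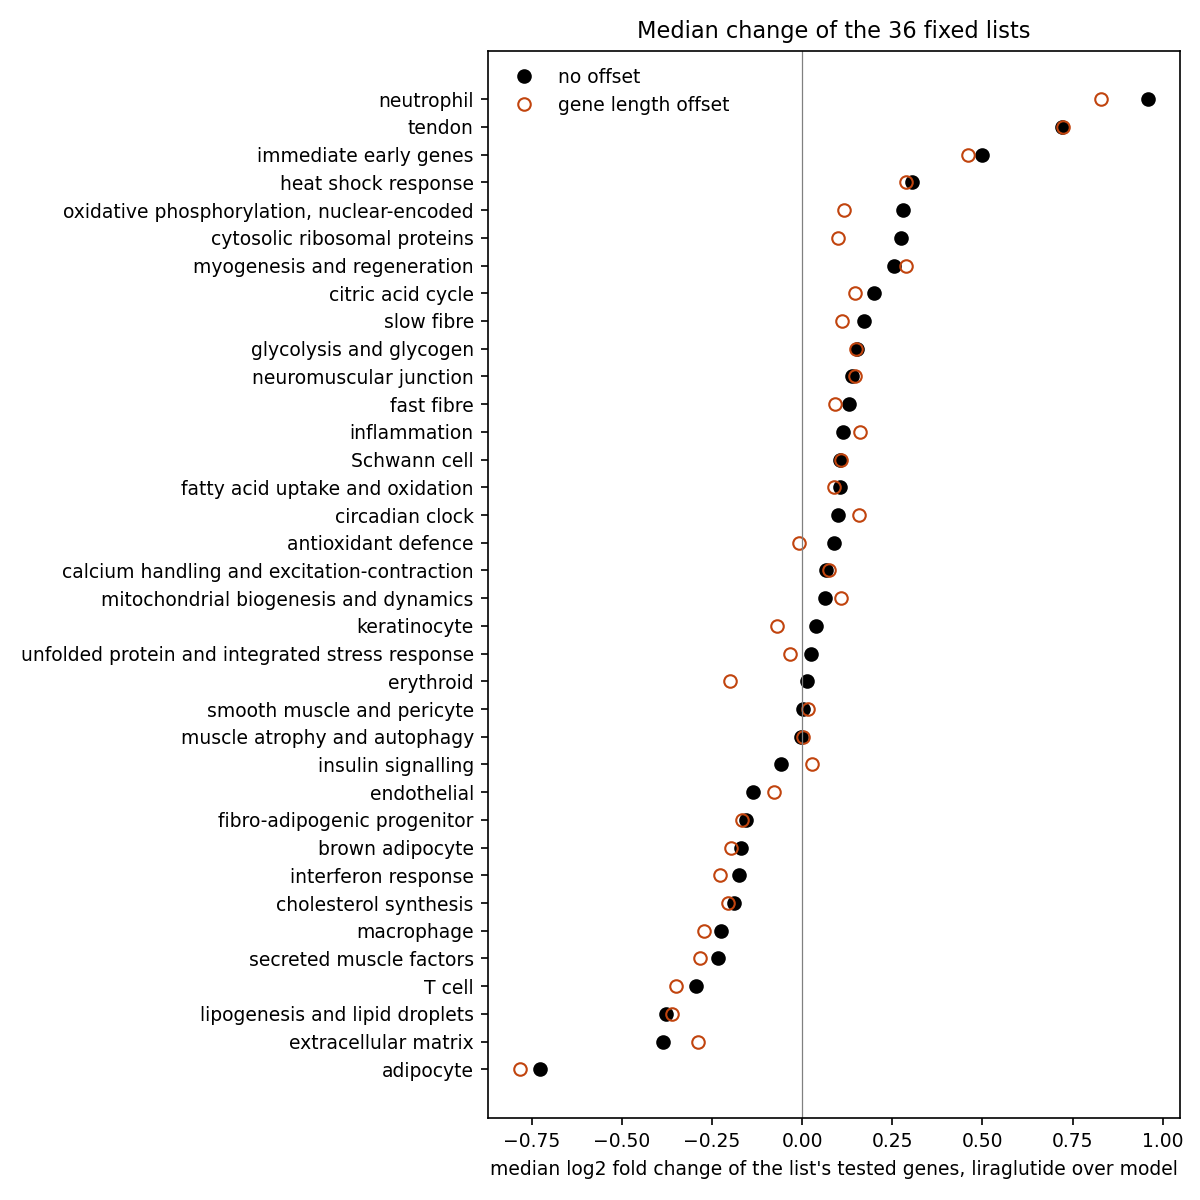
Median log2 fold change (liraglutide over model) of the tested genes of the 36 lists, without an offset (filled) and with a gene length offset (open). The oxidative phosphorylation and ribosomal medians moved from 0.28 and 0.27 to 0.12 and 0.10, while the adipocyte and tendon lists kept the lowest median and the second highest.

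In all, camera called 13 of 23 gene lists (9 up, 4 down) and 5 of 13 cell type lists (2 up, 3 down). With an estimated correlation 0 of either were called, at an unadjusted p under 0.05 for 7 and 0. Fry called 10 and 2, of which 9 and 1 were among those of camera, and the exact permutation test 0 and 0 after adjustment, with 8 and 1 at the smallest unadjusted p of 0.0286 (0.114 adjusted, so the design left little room for a call). Among 2456 GO and KEGG terms, camera called 80 up and 67 down (0 with an estimated correlation, adjusted p = 0.916 at the least, 122 unadjusted). Among the KEGG terms alone, Ribosome (131 genes, 81 higher, camera adjusted p = 1.26e-36) and Oxidative phosphorylation (108 genes, 66 higher and 1 lower, 7.5e-31) led upward. Each was at camera adjusted p = 0.916 with an estimated correlation. Downward, Protein digestion and absorption (79 genes, 18 lower, 1 higher; 1.54e-08), which holds the collagens, Fat digestion and absorption (29 genes, 11 lower, 2 higher; 2.5e-05) and PPAR signaling (60 genes, 18 lower, 3 higher; 0.0017) were called, again at adjusted p = 0.916 with an estimated correlation. The first principal component held 33.3% of the variance and separated the groups, and the second held 18.3%.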

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

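All tests of explanations in this part, and the counts over other splits of the libraries, were chosen after the results had been seen. The 2 tests of the epididymis transcripts were moreover revised after their first outcomes, and each outcome is given.

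Epididymis transcripts were higher in each model library than in the liraglutide libraries for 12 markers, led by Gpx5 and Adam7. RNA of a single epididymal source in fixed proportions was tested first with all 21 markers that had at least 20 counts: their chi-square per degree of freedom over the model libraries was 4.223, above 98.4% of 1000 random gene sets (median 2.35, the bound), which argued against such a source for all markers, with Crisp1 giving 41.5% of the chi-square. The test was then limited to the 12 markers called lower, with the bound moved from the 50th to the 95th percentile. The value was 1.638 (14.9% of random sets at or below). A call in these same libraries favours markers with even counts within the model group, unlike the random sets. This value therefore cannot decide, and the question stayed open. A response of muscle to liraglutide gave an exact permutation p of 0.05714 for the summed markers without Crisp1, which rests on markers outside the 12 in liraglutide 2; the first form of this test counted a p over 0.05 against a response, and it was reworded because a missed threshold excludes nothing, so this too stayed open. Material carried over at dissection, of varying make-up, might explain the markers. A lower sum with liraglutide would follow from such material in the model libraries as well as from an effect of treatment. The permutation test therefore could not tell them apart.

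Adipocyte markers were lower in the liraglutide libraries. A smaller share of fat cells with unchanged expression in each would lower all markers alike if no other cells made them. The log2 fold changes of 14 markers differed more than their errors allowed (Q 57.1, p = 1.7e-07 from the chi-square tool of R), from 0.20 for Cfd to -1.59 for Lep. This argued against an equal fall of all 14 markers. The test took the markers as varying independently, whereas their estimated correlation was 0.599, so its p is not exact. It also took them as made by fat cells alone, and therefore cannot decide whether expression in fat cells changed. A smaller share of fat cells, with or without altered expression in them, may still hold. Fat carried in together with epididymal material was tested by the ratio of adipocyte excess to epididymis counts in the model libraries, which ran from 6.00 to 19.8, a quotient of 3.294; ranges of 2 SD of the liraglutide libraries' adipocyte level to each side overlapped, and this stayed open. Liraglutide 2 had 43.8 CPM of epididymis markers without Crisp1, beside 43.2 in model 2, but 1051 CPM of adipocyte markers against 2127. The epididymis sums came from different markers. The 12 called lower held 38 counts in liraglutide 2 and 456 in model 2, and the others without Crisp1 held 762 and 194. This pair of libraries therefore cannot show whether fat came with the epididymal material of the model libraries.

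Oxidative phosphorylation and ribosomal protein genes were higher in the liraglutide libraries. A trend with gene length and GC content of the smooth form fitted here was argued against as the whole cause. After the offset the list means still differed by 0.1298 (pooled SD 0.0192) and 0.1111 (pooled SD 0.0270). The groups did not overlap (exact permutation p = 0.0286 each, the smallest possible). The fitted trend could account for about the rest of the 0.273 and 0.268 seen without it. A trend steeper among short genes than the smooth was not excluded, since the lists' median lengths were 795 and 814 bases. A larger share of muscle fibre RNA was tested by the oxidative phosphorylation mean less the fast fibre mean, which differed by 0.07702 after the offset (exact permutation p = 0.0571) and by 0.131 without it (exact permutation p = 0.0286), and stayed open.

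Among the 35 splits of the libraries into 4 and 4, the real one was the 1 split with as many as 1333 called genes (highest other 3) and the 1 split with as many as 589 genes by size (highest other 316). For gene lists 8 splits had at least the real count of 13 (highest other 17), for cell type lists 17 had at least 5 (highest other 10), and for terms 6 had at least 147 (highest other 331), so for these 3 counts chance was not excluded. Each of the 7 other splits with at least 13 gene lists kept 3 libraries of a group together. The splits with 2 libraries of each group on each side reached at most 10 gene lists, 10 cell type lists and 227 terms. The split with 331 terms set liraglutide 1, model 1, model 3 and model 4 against the rest, more than the real split, and this structure among the libraries was not traced to a cause.

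A library stood apart from the other 3 of its group in 26 of 289 groups checked, where 14.5 are given by chance at about 1 in 20 (8 of 44 library measures, 6 of 72 list means and 12 of 173 named genes). The library measures that stood apart include epididymis, Crisp1, mesothelium, hepatocyte and Alb counts, partly nested and chosen after such values had been seen. The excess over 14.5 is therefore not a test of chance. Liraglutide 2 was the high library 7 times and model 2 the low library 5 times. Liraglutide 2 had 15846 genes with a count against 15501 to 15539 in its group. It also had 3435 epididymis counts against 65 to 96, and 800 against 63 to 80 without Crisp1. Crisp1 itself stood at 2635 against 2 to 20, and mesothelium markers at 561 against 110 to 126. Model 3 had 15102 hepatocyte counts against 3438 to 4148 and 5757 of the albumin gene Alb against 61 to 142. The first component of model 4 was -15.29 against -22.21 to -21.89.

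On the log2 CPM scale, the fatty acid list mean was 7.625 in liraglutide 3 (others 7.41 to 7.437) and 7.481 in model 3 (7.393 to 7.395). The insulin signalling mean was 6.037 in liraglutide 2 (6.245 to 6.272) and 6.308 in model 4 (6.271 to 6.276). The cholesterol synthesis mean was 3.143 in model 2 (3.237 to 3.243), and the macrophage mean 4.491 in liraglutide 1 (3.602 to 3.662). In model 2, Comp stood at 2.962 (4.131 to 4.263), Lcn5 at 0.9562 (2.162 to 2.402), Lcn9 at 0.5058 (0.9476 to 0.9711) and Retnlg at -2.005 (1.672 to 1.971). Cst11 stood at -2.483 in liraglutide 4 and Defb20 at -1.551 in liraglutide 2, against -3.07 in the others, which is the value of 0 counts. Ndufb8 stood at 8.509 in liraglutide 2 (8.456 to 8.464), Cox6a2 at 9.469 in liraglutide 3 (9.36 to 9.374) and Rps14 at 8.089 in liraglutide 3 (7.997 to 8.008). Mstn stood at 5.933 in model 4 (6.217 to 6.25) and Otop1 at -0.9027 in model 3 (0.2909 to 0.4382).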

How the results depend on the processing

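The offsets, limma on log2(FPKM + 1), the joint omission of 2 libraries and the omission of the epididymis markers were chosen after the data had been seen, the other alternatives before. The 1333 calls became 2396 in limma on FPKM rescaled to a common sum and 820 with quantile normalization in limma. They became 773 with a gene length offset, 459 with a length and GC offset and 697 without liraglutide 2 and model 3. Omission of single libraries gave 615 to 1231. Median-ratio scaling gave 1309, a robust prior 1370 and protein-coding genes alone 1328. Of the 69 called genes named by the fixed rule, 29 lost their call with the length and GC offset and 18 with the length offset. Quantile normalization in limma ended 17 of 68 such calls and reversed the sign of 1. The limma alternatives change the tool as well as the setting named. The cause of these shifts was not tested.

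The 589 genes past the looser criterion became 952 without a low-count filter and 301 with an FPKM of at least 1 in 4 libraries. In limma they became 209 with quantile normalization, 232 without the trend, 229 with array weights and 235 on log2(FPKM + 1). Omission of single libraries gave 539 to 689. The larger number without a filter follows from the added low-count genes; the other causes were not tested.

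The 13 gene lists became 0 in camera with an estimated correlation (7 at an unadjusted p under 0.05), 0 in the exact permutation test (8 at the smallest unadjusted p of 0.0286) and 8 with quantile normalization in limma. Omission of single libraries gave 12 to 17. The 5 cell type lists became 0 with an estimated correlation (0 unadjusted), 2 in fry (adipocyte, and neuromuscular junction in place of the other 4) and 0 in the exact permutation test, and 4 to 5 without single libraries. The 147 terms became 0 with an estimated correlation (122 unadjusted), 94 in limma on log2(FPKM + 0.1), 71 after rescaling, and 92 each without the trend, with array weights and on log2(FPKM + 1). Omission of single libraries gave 119 to 193. The 0 of the permutation test was nearly set by the design, since with 36 lists the smallest exact p came to 0.114 after adjustment; the cause of the other shifts was not tested.

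With quantile normalization in limma the median log2 fold change turned to -0.0027 for the fatty acid list, -0.013 for glycolysis and -0.029 for fast fibre, and that of Mylpf to -0.031; the cause was not tested.

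With the replicate number as a block there were 1035 calls (515 higher, 520 lower), and 650 with the length offset and the block. Deviations of libraries sharing a number correlated at 0.149, -0.0275, 0.143 and 0.0648, the best match for 2 of 4, so the numbers gave no evidence of pairing and the block stayed out.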

Other observations

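Transcripts of several other tissues were present in single libraries, and those of the epididymis in each model library. Lists of such markers were chosen after some of the genes had been seen. Hepatocyte markers summed to 127 ± 19.9 CPM in the liraglutide and 411 ± 337 CPM in the model libraries (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0667 over 28 library measures), a sum led by model 3 and by the transferrin gene Trf. Trf, which many tissues express, had 1839 to 2230 counts in the liraglutide and 3048 to 3900 in the model libraries and fell by 0.92 on the log2 scale. Model 3 had 5757 counts of Alb and 727 of Apoa1, a lipoprotein gene, against 61 to 142 and 143 to 153 in the other model libraries. Mesothelium markers summed to 12.9 ± 11.9 against 10.6 ± 1.75 CPM (exact permutation p = 1), testis markers to 2.61 ± 1.64 against 2.67 ± 0.825 CPM (exact permutation p = 0.943), and seminal vesicle and prostate markers to 0.263 ± 0.310 against 0.701 ± 0.421 CPM (exact permutation p = 0.171). With Crisp1 kept, epididymis markers summed to 50.6 ± 91.8 against 68.1 ± 12 CPM.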
